A study of Sorangium sp. with 19 samples.

How the data were processed

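RNA from shaken cultures of Sorangium sp. So ce836 was sequenced at 5 sampling days (days 4, 7, 11, 14 and 21), with 19 libraries in all. Per the labels' protocols, pre-cultures were diluted into fresh medium, each growth period had its own flasks, residual DNA was digested, ribosomal RNA was depleted, and libraries were made with a stranded kit. The labels call the replicates biological and the flasks separate, so replicates were treated as separate cultures. A day 0 growth period named in the protocol was not analysed here.

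The authors deposited a table of raw counts per locus tag for each library, with no normalisation. The submitters' processing notes name fastp 0.20.1, BWA 0.7.12, SAMtools 0.1.19, HTSeq and DESeq2 1.32.0. The genome build, the annotation, the HTSeq version and the strand setting of the counting are not given in the sources used here, so reads of overlapping or antisense genes may not be told apart, and near-identical gene copies may share or lose reads. The authors also deposited a table of normalised signal values, which equals the raw counts divided by 1 size factor per library (between 0.214 and 2.13); it was used only to check the counts. Each count file ends with 5 summary rows that name no gene, and these stayed out of library sizes and tests. Of all reads, 42.7% to 67.8% were set aside for low alignment quality and at most 0.0363% were not aligned. Of the reads assigned to a gene, to no feature or to several, 2.71% to 8.03% had no feature and 1.28% to 4.05% were ambiguous.

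Total counts per library were 4204641 to 13164839. Intervals and floors cover counting error only, without the spread between cultures, and the reads carry no molecular identifiers. The floor was set at 3 counts per library. Within each day, the counts of every pair of libraries differed by more than sampling noise (chi-square per degree of freedom between 9.35 and 143.8 over 28 pairs), so no library was taken as a copy of another.

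Counts were analysed with edgeR 4.0.16 in R 4.3.3. Tags were kept by filterByExpr with the day as group, which left 8540 of 10707 tags and at least 99.9% of the counts of each library. TMM factors, robust dispersions and the quasi-likelihood F-test were used in 1 fit of all 19 libraries with 1 coefficient per day and no block. Tags were called at a Benjamini-Hochberg adjusted p below 0.05 over the tested tags, all tests were two-sided unless stated, and the SE of a log2 fold change is its size divided by the square root of F. Levels are CPM with TMM-scaled library sizes. These tests, with the comparisons of consecutive days and the joint test, were fixed before the data were examined. The comparison of day 21 with day 4, the peak calls over all tags, the blocks and the reversals were chosen after seeing the data.

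A peak was called where the day of highest mean exceeded each of the 4 other days, taking the largest of the 4 p-values and adjusting it over the tested tags. A block is a run of at least 5 consecutively numbered tags, each called and changed at least 2-fold in 1 direction (for peaks, each called on the same day). Its tags were chosen because they were called, so no separate p is given for a block. The number of tags in blocks was compared with 10000 random placements of the called tags. Random placement takes the tags as unrelated, so its p bears on clustering alone and not on the spread between cultures. For each direction of a comparison the longest block, or all of equal length, and the block with the largest median change are described.

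Named tags follow a rule fixed before the data were examined for the case that no annotation matches: at most 2 tags up and 2 down per comparison. They are those with the largest log2 fold change among called tags with a mean of at least 10 CPM over the 2 days and no overlap between the days' CPM ranges. The gene lists, the biosynthetic loci and the core biosynthetic genes that were planned need gene products, which the files do not pair with the tags, and were not analysed here. Blocks and the most abundant tag were singled out after their values were seen.

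The edgeR steps were tested on simulated counts for 8540 tags, of which 200 were changed by a known factor. False calls numbered 12 of 192 calls (6.25%), 5 of 157 (3.18%), 6 of 147 (4.08%) and 6 of 157 (3.82%) for the 4 consecutive comparisons. For day 21 against day 4 they numbered 15 of 183 (8.2%). The shares for day 7 and for day 21 against day 4 lay above the share that the threshold aims at. Of 200 tags with a simulated 4-fold peak on day 11, 94% were called, with 1 false call. Alternatives were DESeq2 1.42.0, size factors from DESeq2's method, upper-quartile factors, total counts alone, removal of the 10 most abundant tags, other count filters, fits of only the 2 days compared, a 2-fold threshold, a replicate block, other block lengths and leaving out each library in turn. Permutation tests and figures used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.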

Results

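Gene expression was followed over a batch culture of Sorangium sp. So ce836, a soil-dwelling myxobacterium of a genus known for its natural products. The study asked how transcription of biosynthetic gene clusters changes as the culture ages. RNA was taken from separate flasks on 5 sampling days, with 4 cultures on day 4, 5 on day 7, 3 on day 11, 4 on day 14 and 3 on day 21. The 19 libraries gave counts for 10707 numbered genes, called locus tags here. The files do not pair these tags with gene names or products, so which tags belong to a biosynthetic gene cluster was not analysed here. Consecutive tag numbers were read as neighbouring genes, and a run of at least 5 neighbours that all passed the test and changed at least 2-fold the same way is called a block.

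Total counts per library lay between 4204641 and 13164839. A few tags held much of each library. The 10 most abundant tags of a library took 57.6% ± 8.09 of the counts on day 4 (SD, n = 4), 58.3% ± 3.33 on day 7 (n = 5), 65.4% ± 0.623 on day 11 (n = 3), 77.8% ± 3.38 on day 14 (n = 4) and 49.1% ± 3.07 on day 21 (n = 3). NQZ70_08794 alone held 36.3% ± 1.83 of the counts on day 14 and 18.4% ± 2.51 on day 21. Counts outside these 10 tags, which carry the comparisons of the other genes, ranged from 725628 in day 14 replicate 4 to 6830283 in day 4 replicate 2. Day 14 was therefore the day of lowest effective depth, and 3 counts corresponded to between 0.145 and 1.49 counts-per-million units (CPM) across the libraries. Reads set aside by the counting step for low alignment quality were also highest on day 14, at 63.8% ± 4.01 of all reads, and lowest on day 21, at 43.6% ± 0.916.

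Most of the measured transcriptome changed during the culture. Of 8540 tags with enough counts to test, 7871 (92.2%) differed between the sampling days at adjusted p < 0.05 in edgeR's joint quasi-likelihood test. The step from day 4 to day 7 changed 6038 tags, that from day 7 to day 11 changed 5066, that from day 11 to day 14 changed 3480 and that from day 14 to day 21 changed 3825. These counts also follow the number and depth of the libraries. In simulated data with 200 changed tags, 2-fold changes were recovered in 83%, 60%, 56% and 61% of cases for these 4 steps, and 4-fold changes in 97%, 92%, 85% and 90%. The real comparisons called 40.7% to 70.7% of the tags. With only 200 of 8540 tags changed, the adjusted p is a stricter threshold, so these rates do not give the power behind the real counts.

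**Figure D1:**
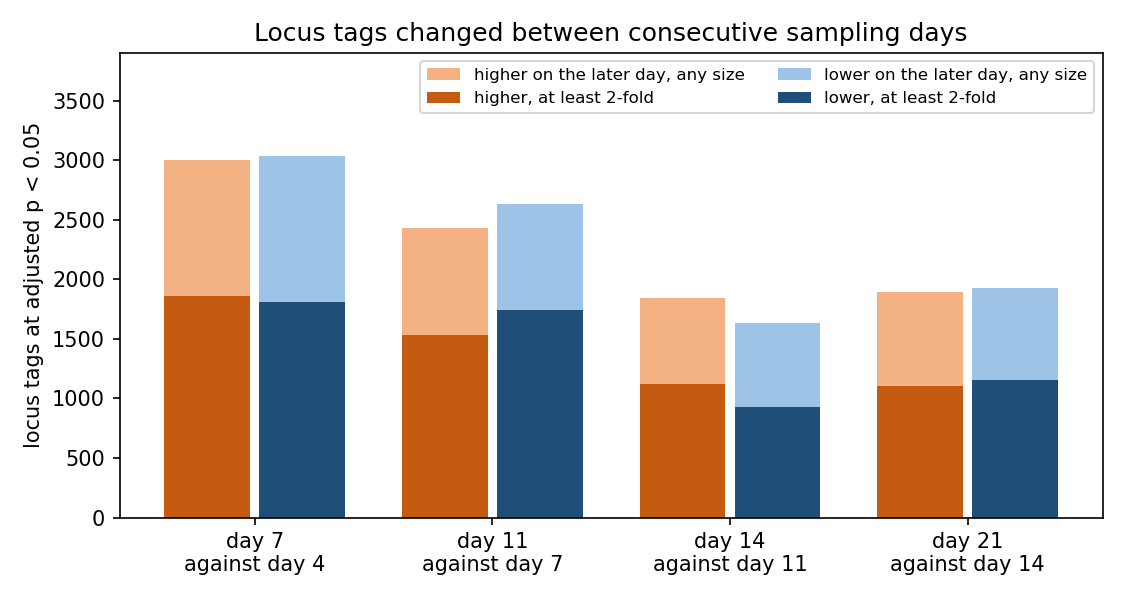
Number of locus tags (vertical axis) called at adjusted p < 0.05 in each of the 4 comparisons of consecutive sampling days (horizontal axis), split by direction, with the darker part of each bar for changes of at least 2-fold. The bars for day 7 against day 4 are the tallest, at 2999 tags higher and 3039 lower on the later day.

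Between day 4 and day 7, 2999 tags rose and 3039 fell, 1860 and 1807 of them by at least 2-fold. NQZ70_04403 rose from 0.191 ± 0.0493 CPM (SD, n = 4) to 263 ± 48.5 CPM (n = 5), a log2 fold change of 10.38 (SE 0.30, adjusted p = 4.8e-20). Its neighbour NQZ70_04404 rose from 0.191 ± 0.146 to 269.9 ± 45.3 CPM, by 10.22 on the log2 scale (SE 0.37, adjusted p = 7.4e-18). NQZ70_06639 fell from 423 ± 116 to 3.66 ± 1.3 CPM, a log2 fold change of -6.85 (SE 0.34, adjusted p = 5e-14). Its neighbour NQZ70_06640, with 2168 ± 439 CPM on day 4, fell to 30.9 ± 11.0 CPM (log2 fold change -6.13, SE 0.33, adjusted p = 9.5e-14).

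Neighbouring tags moved together at this step. Blocks held 381 of the tags that rose at least 2-fold, in 55 blocks, and 326 of those that fell, in 47 blocks. The longest rising block, NQZ70_05574 to NQZ70_05587, had 14 tags with a median log2 fold change of 3.80, and its summed level went from 7.24 ± 0.798 CPM on day 4 to 145 ± 32.5 CPM on day 7. The strongest rise was in NQZ70_05065 to NQZ70_05069, 5 tags that went from 1.71 ± 0.576 to 362 ± 89.3 CPM together (median log2 fold change 8.27). Among falling blocks, the longest was NQZ70_05264 to NQZ70_05278 with 15 tags (median -1.67), and the strongest fall was in the 7 tags NQZ70_06313 to NQZ70_06319, from 357 ± 33.7 to 32.6 ± 1.54 CPM (median -4.20). When the called tags were placed at random among the tested tags, blocks held on average 10.6 rising and 9.26 falling tags (permutation test, 10000 shuffles, one-sided p = 0.0001 in each direction, the smallest these shuffles can give). Here and in the same tests below, p shows only that called tags were not scattered at random. It does not measure the spread between cultures, and variation that neighbouring tags share within a culture was not separated from a change with the day. Without TMM scaling the median tag shifted by -0.36 on the log2 scale, and the calls split into 2072 higher and 3793 lower, with 275 and 609 in blocks; upper-quartile factors put 355 rising and 409 falling tags in blocks, and a filter of 50 counts in 3 libraries 186 and 223, while each named tag kept its direction in all alternatives and each named block its direction under all scalings. With single libraries left out, the log2 fold change of NQZ70_04404 (14 counts on day 4) ran from 10.02 to 10.85 and that of NQZ70_04403 (12 counts) from 10.3 to 10.5. The mean day 4 levels of both tags lay within the range of the 3-count floor in the day 4 libraries (0.145 to 0.259 CPM), so the size of these rises is uncertain.

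Between day 7 and day 11, 2435 tags rose and 2631 fell, 1529 and 1741 of them by at least 2-fold. The pair that had risen most on day 7 fell to mean levels below the floor of 3 counts (0.409 to 0.462 CPM in the day 11 libraries). How near these came to the day 4 levels, both 0.191 CPM, is therefore uncertain. NQZ70_04404 fell from 269.9 ± 45.3 CPM (SD, n = 5) to 0.253 ± 0.322 CPM (n = 3), with a log2 fold change of -10.07 (SE 0.46, adjusted p = 1.5e-15), and NQZ70_04403 fell to 0.346 ± 0.245 CPM (log2 fold change -9.57, SE 0.35, adjusted p = 2.5e-17). In the other direction, NQZ70_01129 rose from 4.26 ± 1.48 to 296 ± 139 CPM (log2 fold change 6.10, SE 0.33, adjusted p = 9.8e-13). NQZ70_09520 rose from 1.17 ± 0.449 to 58.7 ± 37.0 CPM (log2 fold change 5.61, SE 0.41, adjusted p = 3.1e-10).

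Blocks held 419 tags that fell at least 2-fold, in 54 blocks, and 143 that rose, in 21 blocks. The longest falling block was NQZ70_09261 to NQZ70_09284, 24 abundant tags whose summed level went from 7665 ± 1468 to 1166 ± 206 CPM (median log2 fold change -2.71). NQZ70_07024 to NQZ70_07028 fell most, from 344 ± 66.5 to 1.57 ± 0.289 CPM (5 tags, median -7.75). Shared over 5 tags, this day 11 level lay below the floor of 3 counts per tag (0.409 to 0.462 CPM), so the size of the fall is uncertain. The longest rising block, NQZ70_05267 to NQZ70_05291, had 25 tags and went from 1903 ± 433 to 6767 ± 2936 CPM (median 1.69), with the 3 day 11 cultures spread between 4255 and 9994 CPM. NQZ70_05253 to NQZ70_05257 rose from 7.66 ± 2.50 to 66.1 ± 16.3 CPM (5 tags, median 2.94). Random placement gave on average 4.15 rising and 7.69 falling tags in blocks (permutation test, 10000 shuffles, one-sided p = 0.0001, the smallest possible, in each direction). Without TMM scaling the median tag shifted by -0.64 and the calls split into 1246 higher and 4133 lower, with 50 and 901 tags in blocks; the named tags and blocks kept their direction. The day 11 levels of the falling pair rest on 5 and 7 counts, and without day 11 replicate 3 their log2 fold changes were -11.71 and -10.22.

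**Figure D2:**
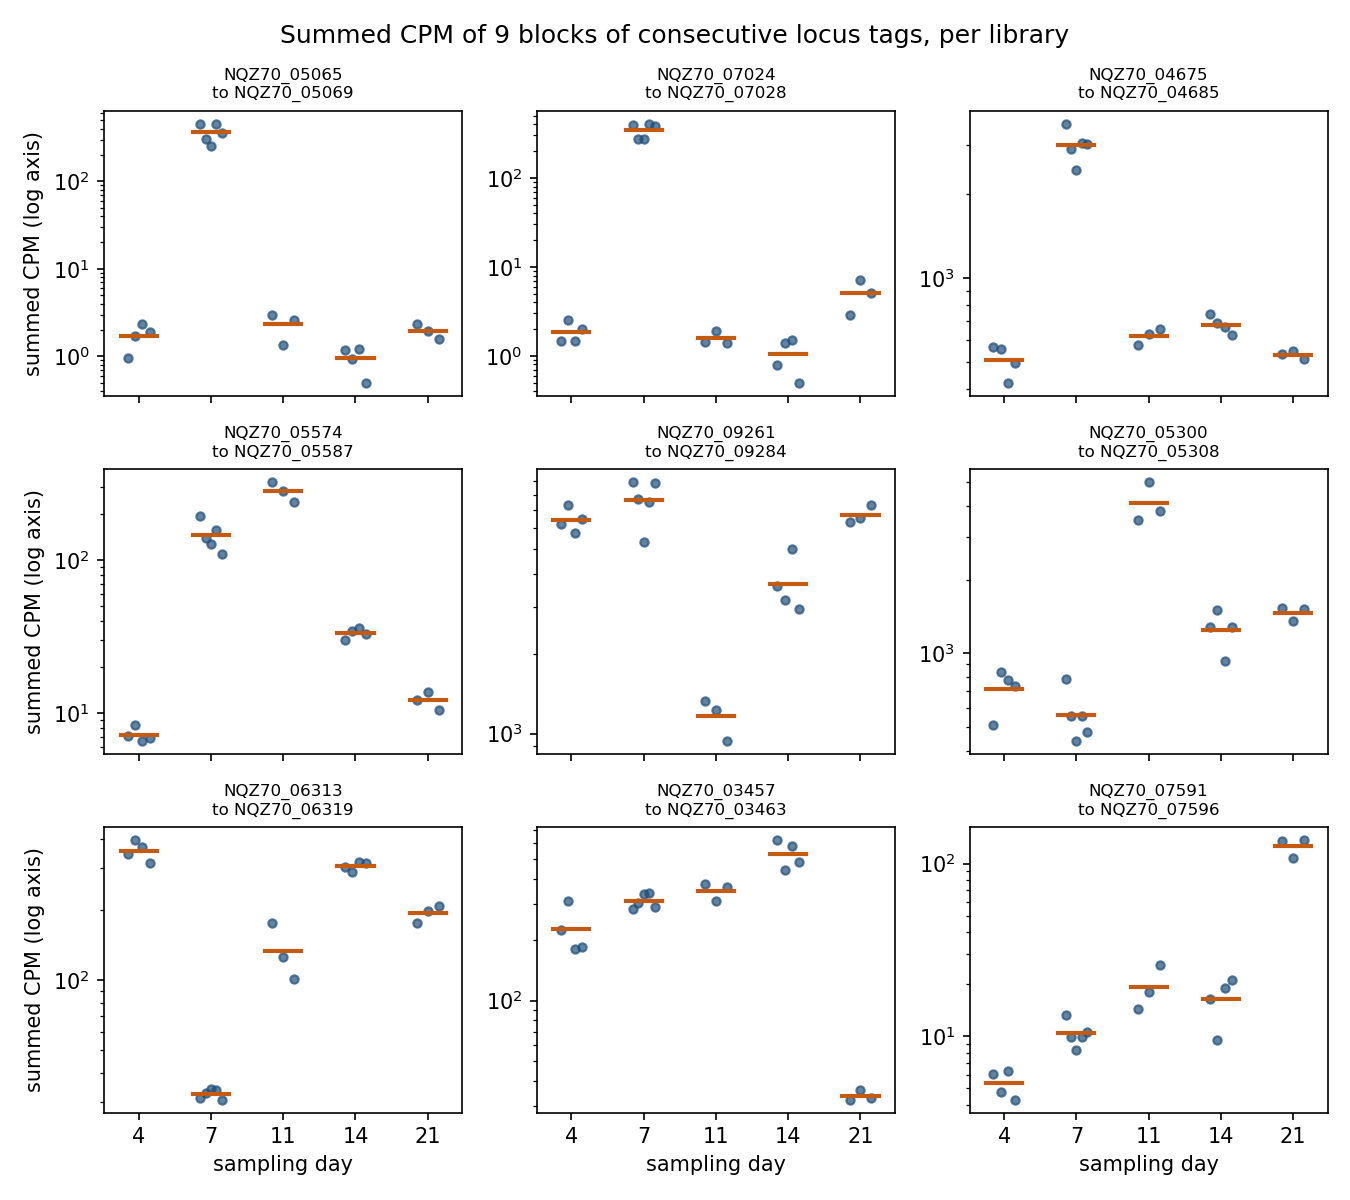
Summed CPM per library (vertical log axis) against sampling day for 9 of the named blocks, with 1 point per library and a line at the mean of each day. NQZ70_05065 to NQZ70_05069 averaged 362 CPM on day 7 and between 0.953 and 2.33 CPM on the other days.

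Between day 11 and day 14, 1847 tags rose and 1633 fell, 1120 and 927 of them by at least 2-fold. NQZ70_02361 fell from 1135 ± 384 CPM (SD, n = 3) to 12.7 ± 8.92 CPM (n = 4), a log2 fold change of -6.53 (SE 0.45, adjusted p = 7.4e-10). NQZ70_05574, the first tag of the block that had risen on day 7, fell from 204 ± 31.9 to 3.06 ± 0.907 CPM (log2 fold change -6.10, SE 0.27, adjusted p = 7.9e-15). NQZ70_08416 rose from 1.85 ± 0.558 to 26.0 ± 6.50 CPM (log2 fold change 3.78, SE 0.29, adjusted p = 1.9e-10), and NQZ70_06317 from 4.81 ± 2.19 to 65.3 ± 21.3 CPM (log2 fold change 3.75, SE 0.30, adjusted p = 3.9e-10).

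Blocks held 120 rising tags in 17 blocks and 68 falling tags in 11 blocks. The 24 tags NQZ70_09261 to NQZ70_09284 rose from 1166 ± 206 to 3678 ± 897 CPM (median log2 fold change 1.57). NQZ70_02062 to NQZ70_02066 rose from 37.4 ± 17.4 to 227 ± 19.8 CPM (5 tags, median 2.41). The longest falling block, NQZ70_05300 to NQZ70_05308, went from 4113 ± 797 to 1249 ± 237 CPM (9 tags, median -1.68), and NQZ70_07465 to NQZ70_07471 went from 1801 ± 458 to 131 ± 15.2 CPM (7 tags, median -3.57). Random placement gave on average 0.892 rising and 0.374 falling tags in blocks (permutation test, 10000 shuffles, one-sided p = 0.0001, the smallest possible, in each direction). The balance of rising and falling tags in blocks did not hold: they numbered 60 and 80 without day 14 replicate 3, 71 and 83 without day 14 replicate 1, 95 and 106 without day 14 replicate 4, 94 and 84 under DESeq2 size factors, and 84 and 92 after removal of the 10 most abundant tags. Without TMM scaling the median tag shifted by -0.27 and the calls split into 945 higher and 2293 lower, with 49 and 149 in blocks; the named tags and blocks kept their direction under each scaling.

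Between day 14 and day 21, 1894 tags rose and 1931 fell, 1106 and 1151 of them by at least 2-fold. NQZ70_00396 rose from 5.86 ± 1.59 CPM (SD, n = 4) to 199 ± 57.1 CPM (n = 3), a log2 fold change of 5.14 (SE 0.53, adjusted p = 1.8e-07). NQZ70_09072 rose from 1.82 ± 0.776 to 45.4 ± 8.77 CPM (log2 fold change 4.62, SE 0.31, adjusted p = 1.4e-11). NQZ70_10577 fell from 26.0 ± 5.66 to 0.540 ± 0.369 CPM (log2 fold change -5.58, SE 0.53, adjusted p = 4.2e-08), and NQZ70_09772 from 44.6 ± 5.69 to 0.957 ± 0.529 CPM (log2 fold change -5.54, SE 0.39, adjusted p = 2.5e-10).

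Blocks held 132 rising tags in 21 blocks and 79 falling tags in 14 blocks. NQZ70_05263 to NQZ70_05278, which covers the longest block that fell on day 7, rose from 639.6 ± 89.4 to 1749.7 ± 157 CPM (16 tags, median log2 fold change 1.52). NQZ70_07591 to NQZ70_07596 rose from 16.5 ± 5.08 to 127 ± 16.3 CPM (6 tags, median 3.52). The longest falling blocks had 8 tags each: NQZ70_05807 to NQZ70_05814 fell from 1355 ± 86.2 to 173 ± 61.9 CPM (median -2.60) and NQZ70_10180 to NQZ70_10187 from 4378 ± 402 to 1945 ± 145 CPM (median -1.40). NQZ70_03457 to NQZ70_03463 fell from 533 ± 84.7 to 33.8 ± 2.12 CPM (7 tags, median -3.90). Random placement gave on average 0.822 rising and 1.02 falling tags in blocks (permutation test, 10000 shuffles, one-sided p = 0.0001, the smallest possible, in each direction). This comparison depended most on the scaling: without TMM scaling the median tag shifted by 1.44 and 6878 tags were called, 6621 higher and 257 lower, with 2774 and 7 in blocks. The median of NQZ70_10180 to NQZ70_10187 was then 0.09, so its fall depended on the scaling, and that of NQZ70_05807 to NQZ70_05814 was -1.15, while the named tags and the other named blocks kept their direction; DESeq2 size factors gave 138 rising and 56 falling tags in blocks, removal of the 10 most abundant tags gave 143 and 51, no count filter gave 169 and 51, and leaving out day 14 replicate 2 gave 125 and 49.

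**Figure D3:**
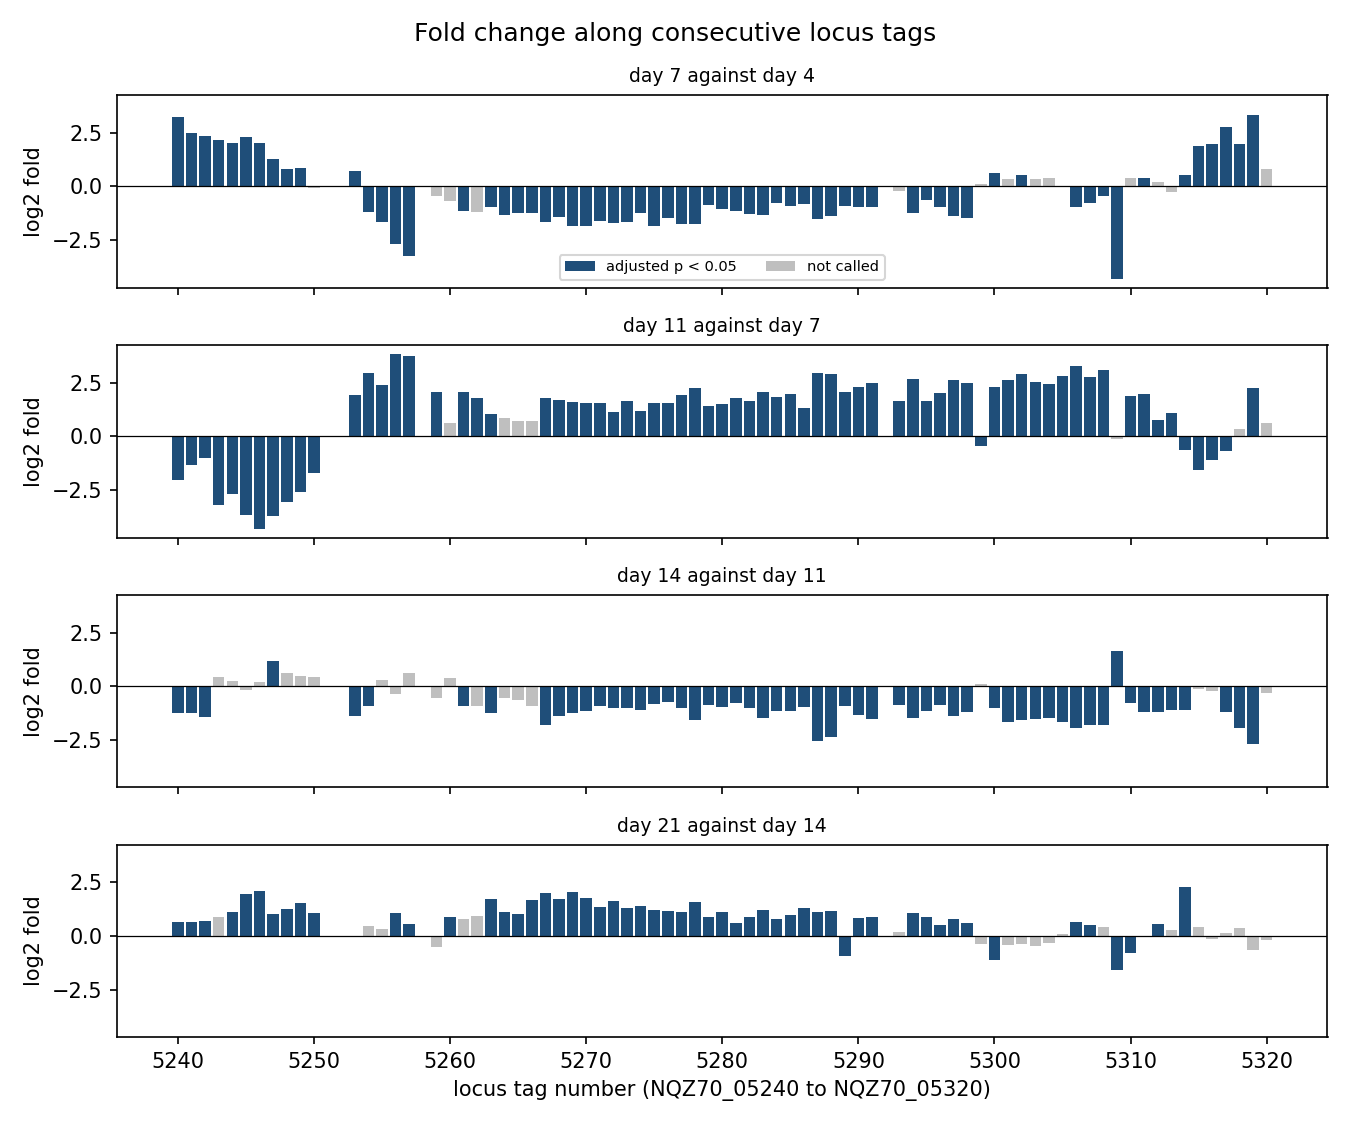
Log2 fold change (vertical axis) of tags NQZ70_05240 to NQZ70_05320 in order of their number (horizontal axis), for the 4 comparisons of consecutive days, with called tags in dark blue and the others in grey; gaps are tags with too few counts to test. The block NQZ70_05267 to NQZ70_05291 lies above 0 in day 11 against day 7, with a median of 1.69.

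Many tags were highest on a single day. A peak was called where a tag's day of highest mean exceeded each of the 4 other days, and 2951 tags (34.6% of those tested) had one. Day 4 had 1004 such tags, day 7 had 708, day 11 had 709, day 14 had 182 and day 21 had 348. Peaks at least 4-fold above the next highest day numbered 66, 151, 34, 5 and 38 on these days. The power to call a peak depends on the depth and the number of cultures of each day, so the low number on day 14 was not separated from its low depth. Peaks per day and peak blocks were counted under TMM scaling only. Total counts alone gave 3067 peaks in all, and the median tag then shifted by 1.44 for day 21 against day 14. The split over the days and the peak blocks may therefore depend on the scaling. Tags peaking on day 7 formed 22 blocks with 161 tags, where random placement gave 0.0988 tags on average (permutation test, 10000 shuffles, one-sided p = 0.0001, the smallest possible). The longest had 11 tags: NQZ70_03000 to NQZ70_03010, at 395.5 ± 78.3 CPM on day 7, and NQZ70_04675 to NQZ70_04685, with a summed level of 508 ± 66.7 CPM on day 4, 2997 ± 403 on day 7, 618 ± 39.3 on day 11, 678 ± 48.3 on day 14 and 529.5 ± 18.9 on day 21 (SD, n = 4, 5, 3, 4 and 3). The longest blocks that peaked on day 4 had 9 tags each: NQZ70_06699 to NQZ70_06707 (294 ± 21.7 CPM), NQZ70_02755 to NQZ70_02763 (1657 ± 348 CPM) and NQZ70_10551 to NQZ70_10559 (574 ± 65.7 CPM). The longest that peaked on day 11 was NQZ70_05300 to NQZ70_05308 (9 tags, 4113 ± 797 CPM), on day 14 NQZ70_04156 to NQZ70_04161 (6 tags, 68.4 ± 8.46 CPM) and on day 21 NQZ70_02441 to NQZ70_02448 (8 tags, 309.8 ± 16.6 CPM).

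Some changes of at least 2-fold were followed by the opposite change at the next step. Of the 1860 tags that rose on day 7, 558 fell on day 11, where independent lists would share 379. Of the 1807 that fell on day 7, 386 rose on day 11, against 324 for independent lists. The values for independent lists take every tag as equally likely to be called, and overlaps in the same direction were not computed. An excess over them therefore cannot be read as a tendency to reverse. Both steps use the day 7 libraries. With these divided between the steps the overlaps were 542 and 531 for rise then fall (372 and 365 for independent lists), and 371 and 390 for fall then rise (332 and 329). In 20 simulations without any change the overlap was 0, which says nothing of what sharing adds among changed tags, since hardly any tag is expected to be called there. Around day 11, 455 tags rose and then fell (166 for independent lists) and 621 fell and then rose (228); the 3 day 11 libraries cannot be divided, so part of the excess may come from their sharing. Around day 14 the overlaps were 191 (151 for independent lists) and 214 (120), and with the day 14 libraries divided they were 140 and 126 for rise then fall (96 and 134 for independent lists), and 154 and 153 for fall then rise (81 and 119). An excess of rise then fall around day 14 was therefore not shown, as the overlap of 126 lay below its independent value. All these overlaps were counted under TMM scaling only. Without it, 945 tags were called higher and 2293 lower for day 14 against day 11. For day 21 against day 14 the calls were then 6621 higher and 257 lower. The overlaps may therefore depend on the scaling, most of all around day 14.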

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

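The tests of the share of reads without a feature were chosen after that share had been seen, and the p given below is not adjusted for the choice of day 11. Chance alone was expected to single out about 7 of the 135 groups of libraries examined for a library far from the rest, and 8 were found.

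Reads without a feature took 7.00% of reads assigned to a gene, to no feature or to several on day 11 (mean, n = 3), and the lowest day 11 library (5.76%) lay above the highest of all other libraries (5.465%; exact permutation test over 969 arrangements, two-sided p = 0.00206). A smaller share of counts in the 10 most abundant tags on day 11 is argued against as the whole cause: 11 of the other libraries had a smaller share than any day 11 library, and against the 5 with a larger share the lowest day 11 library was still higher by 1.96 reads per 100 counts outside those tags. Genomic DNA cannot be told apart on the first test run, which counted 44 tags at 0 in all 3 day 11 libraries with counts in every day 7 library, between the bounds of 10 and 100 set for it. A second test had bounds set after that result. It found under 10 counts over the 3 day 11 libraries in 12.3% of 9207 tags seen on day 7. The excess of reads without a feature would be 70.2 per tag if spread evenly over all tags. These reads lie outside the tags, and how many reads DNA would add to the tags themselves was not computed. The second test argues against DNA as the whole source only if DNA added as many reads to the tags as outside them. Transcripts outside the annotated tags, or a change with culture age, may also contribute and were not tested.

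Reads set aside for low alignment quality were a signal outside the comparisons, with a day 14 mean of 63.8% of all reads. In day 7 replicate 2, 5.298% of reads had no feature (95% Wilson interval 5.286% to 5.31%), against 4.473% to 4.663% in the other day 7 libraries. Ambiguous reads were 1.941% in day 7 replicate 3 (95% Wilson interval 1.933% to 1.949%), below the 2.54% to 2.738% of the others. NQZ70_04404 stood at 1.981 CPM in day 14 replicate 4, from 4 counts in the shallowest library, against at most 0.2325 CPM in the other day 14 libraries. In day 4 replicate 3 NQZ70_09520 was at 1.02 CPM, above 0.4407 to 0.5306 CPM in the others. NQZ70_09072 was at 5.154 CPM in day 7 replicate 3, below 9.042 to 10.5 CPM. The block NQZ70_05267 to NQZ70_05291 summed to 2643 CPM in day 7 replicate 1, above 1501 to 1810 CPM. The block NQZ70_02062 to NQZ70_02066 summed to 256.9 CPM in day 14 replicate 1, above 213.9 to 219.7 CPM. The block NQZ70_02755 to NQZ70_02763 summed to 817.4 CPM in day 14 replicate 3, above 385.2 to 414.8 CPM.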

How the results depend on the processing

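Total-count scaling, removal of the 10 most abundant tags, other block lengths, and all alternatives for blocks, peaks and day 21 against day 4 were chosen after seeing the data. All 448 alternative fold changes of the named tags kept their direction and stayed past the threshold. The balance of higher and lower calls did not hold in any comparison. It turned from 2999 higher and 3039 lower to 3189 and 3129 without a count filter (day 7 against day 4), and with the 10 most abundant tags removed from 2435 and 2631 to 2589 and 2510 (day 11 against day 7), from 1847 and 1633 to 1539 and 1866 (day 14 against day 11) and from 1894 and 1931 to 2077 and 1774 (day 21 against day 14). In blocks it turned for day 7 against day 4, from 381 and 326 to 355 and 409 with upper-quartile factors, and for day 14 against day 11, from 120 and 68 to 60 and 80 without day 14 replicate 3; the cause was not tested. With at least a 2-fold change, calls numbered 3667, 3270, 2047 and 2257 in the consecutive comparisons and 2287 for day 21 against day 4, by construction of the stricter threshold. Total counts alone gave 6878 changed tags for day 21 against day 14, and 951 (day 11 against day 7) and 2781 (day 21 against day 14) tags in blocks; the median tag then shifted by 1.44 in the last comparison and by 0.14 in day 21 against day 4, where the balance turned from 2195 higher and 2377 lower to 2561 and 1537. Upper-quartile factors shifted the median by -0.10 on day 7 against day 4 and by -0.17 on day 21 against day 4. Runs of at least 8 tags held 308, 276, 70 and 42 tags in the consecutive comparisons, and runs of at least 4 held 300 for day 14 against day 11 and 363 for day 21 against day 14. A filter of 50 counts in 3 libraries left 409, 374 and 138 tags in blocks for day 7 against day 4, day 11 against day 7 and day 21 against day 14, with fewer tags tested. DESeq2 called 6012, 5042, 3457, 3865 and 4611 tags in the 5 comparisons. Leaving out each library in turn gave 5694 to 6182, 4462 to 5096, 2966 to 3549, 3278 to 3920 and 3977 to 4722 calls, 7745 to 7943 over the time course and 2664 to 3067 peaks, with 687 to 756, 498 to 611, 140 to 235 and 174 to 242 tags in blocks. Day 14 had the lowest depth outside the most abundant tags, and 4-fold changes between day 11 and day 14 were recovered in 85% of simulated cases. The simulations did not separate depth from the number of libraries.

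With the replicate number as a block, 5883, 4846, 3364, 3666 and 4371 tags were called, 7736 over the time course. No pairing by number was seen in the correlations of deviations. They ran from -0.1 to 0.174 between same-numbered libraries (32 pairs) and from -0.181 to 0.188 between differently numbered ones (111 pairs). Of 19 libraries, 4 correlated best with their own number. A shared pre-culture of same-numbered flasks is not excluded by this. The planned gene list, biosynthetic locus and core biosynthetic gene results and their alternatives were not run, because they need gene products.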

Other observations

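Tests of other splits of the libraries and the test of copy number with independent libraries were chosen after the results were seen, as was the comparison of day 21 with day 4. Over all tags, day 21 resembled day 4 more than the days between did, although single blocks differed. From day 4 to day 21, 2195 tags were called higher and 2377 lower, 1139 and 1148 by at least 2-fold (26.8% of those tested), against 42.9%, 53.3% and 37.7% for days 7, 11 and 14 compared with day 4. The 24 tags NQZ70_09261 to NQZ70_09284 summed to 6420 ± 664 CPM on day 4 (SD, n = 4), 7665 ± 1468 on day 7 (n = 5), 1166 ± 206 on day 11 (n = 3), 3678 ± 897 on day 14 (n = 4) and 6715 ± 531 on day 21 (n = 3). The 7 tags NQZ70_06313 to NQZ70_06319 were nearest to day 4 (357 ± 33.7 CPM) on day 14, at 307 ± 13.5, and stood at 193 ± 16.1 on day 21. Other blocks ended far from day 4: from day 4 to day 21, NQZ70_07591 to NQZ70_07596 went from 5.34 ± 0.958 to 127 ± 16.3 CPM, NQZ70_03457 to NQZ70_03463 from 225 ± 60.3 to 33.8 ± 2.12 and NQZ70_07465 to NQZ70_07471 from 71.6 ± 7.5 to 557 ± 45.2. Total-count scaling gave 2561 tags higher and 1537 lower on day 21.

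The mean correlation with the day 4 libraries across tags, which are not independent replicates, was 0.833 on day 7, 0.784 on day 11, 0.862 on day 14 and 0.906 on day 21. The lowest day 21 library (0.903) lay above the highest of days 7 to 14 (0.878), a gap of 0.0245 (exact permutation test over 455 arrangements, two-sided p = 0.0044, the smallest this design allows). Depth is argued against, since the gap was 0.0222 after every library was thinned to 728184 counts outside the 10 tags most abundant over all libraries. The few most abundant tags are argued against by rank correlations, with a gap of 0.0407. No biological explanation was tested; batches are not given in the sources used here and stay open.

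The change from day 4 also followed the tag number. A cosine fitted along the tags had an amplitude of 0.158 log2 units for day 21 against day 4, lowest near tag number 9496, and 0.161 for day 7 against day 4, lowest near 9395 (permutation tests over 10000 shuffles of segments of 100 tags, adjusted p = 0.0005 each, 5 comparisons in the family; the other 3 adjusted p were 0.94, 0.73 and 0.8). The fit took the tag numbers as a closed circle and capped large fold changes. A few strongly changed blocks and low-count tags are argued against, with amplitudes of 0.11 without tags in runs and 0.182 among tags above the median CPM. Gene copy number, higher near a replication origin in growing cells, and regulation by region cannot be told apart, because the origin's place is not given in the sources used here. Bin medians for day 21 against day 4 replicates 3 and 5 followed the distance from a minimum fitted in other libraries (rank correlation 0.939; 0.927 in a first version with 1 fit for both), which repeats the trend and would hold for any regional gradient.

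In each case only 1 split, the real one, gave a result as large, which argues against chance for the grouping by day. Splits that mix days add the change between days to the spread within groups. Their counts are therefore not the number of calls that chance would give. Where only 35 splits exist, the smallest share that can be reached is 1 of 35, without adjustment over the patterns tested. A batch tied to the sampling day would give the same outcome. For the comparisons of 2 days, fitted on those days alone, the real and highest other counts were 5735 and 3197 for day 7 against day 4 (100 of its splits drawn), 4621 and 0 for day 11 against day 7 (56 splits), 3097 and 421 for day 14 against day 11 (35), 3990 and 1613 for day 21 against day 14 (35) and 4915 and 0 for day 21 against day 4 (35). Over the time course they were 7871 and 743, and for peaks 2951 and 0 (100 splits drawn for each).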
